A study of Rattus norvegicus with 30 samples.

How the data were processed

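RNA from rat cochleae was measured by reverse transcription and real-time PCR on a ready-made panel of oxidative stress and antioxidant defence genes. Per the labels' protocols, 36 rats aged 2 months were divided into an arm given resveratrol plus N-acetylcysteine (20 rats) and an arm given vehicle (16 rats). On day 2 of the treatment a gelatin sponge soaked in kanamycin at 200 mg/ml and furosemide at 50 mg/ml was placed near the round window of 1 ear, and the ear of the other side served as the control of its arm. Cochleae were taken 3 or 21 days after the sponge, which is 5 or 23 days after the first antioxidant dose. The labels give 30 samples in 8 groups. None is named as an ear with a drug-free sponge, so effects of the drugs, the sponge and its placement cannot be told apart.

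3 tables were used. The deposited raw table holds threshold cycles (Ct) for 84 assay rows, with 40 as its ceiling; Ct is an inverse log2 scale, on which 1 cycle less stands for about 2 times more template. 2 of its sample columns match no labelled sample and were not used here. The deposited processed table holds delta Ct values for 79 rows, which are differences in cycles and so on a log2 scale. Another deposited table holds the authors' differences between days, also on the log2 scale. The normalization and the reference genes are not given in the sources used here. A search over 3081 pairs of rows found 1 pair, labelled Xirp1 and Txnrd2 in the processed table, whose delta Ct values sum to 0 in each sample, as they would if their mean was the reference. PCR cycles carry no read depth, so the precision rests on the number of samples and on the level of each assay.

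The row labels of the tables disagree. Across rows, the rank correlation between delta Ct and raw Ct under the same label ran from -0.05 to 0.05 over the 30 samples. With the raw rows put in order of their RefSeq accession it ran from 0.98 to 1. Values are therefore followed by the raw row (plate well) that holds them, and both labels are given at first mention. 5 raw rows have no counterpart in the processed table. Row order also differs between days: the median rank correlation of raw Ct between 2 samples was 0.95 within day 3, 0.98 within day 21 and 0.27 across days. 64 pairs of row orders (well, accession, symbol and plate column, each also undone) gave at most 0.29, the value with the same order on both days. Some of these pairs coincide, since undoing the well order changes nothing. Pairs with different orders on the 2 days gave at most 0.21. Other orders tried while looking at the data did no better. Neither set of gene labels could be settled, so a label below is not a gene identification and no gene functions are given. Symbols come from the processed table, and housekeeping symbols from a match of accessions to the GRCr8 gene table, in which 77 of 84 accessions were found.

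Minus delta Ct as deposited was taken as expression. limma 3.58.1 in R 4.3.3 fitted the means of the 8 groups to all 30 samples, with 22 residual degrees of freedom before moderation, and contrasts were adjusted by the Benjamini-Hochberg method within each of 14 comparisons at 0.05. A row counted as measured when its raw Ct was below 35 in every sample of at least 1 group, which kept all 79 rows. Intervals are 95% confidence intervals. Because row order differs between days, the shared fit pools the spread of different assays, and comparisons across days set rows against each other that need not be 1 assay. Named rows are those past the threshold, at most 25 by size. Where none passed, the 5 with the smallest p are given as values. Some rows that the rule takes are not reported here, and they stay in each fit and count. A gene named in 1 comparison may be given in another, and housekeeping genes may be named. Up to 4 members were allowed per gene list, and rows named outside this rule are said to be so. 15 gene lists were fixed beforehand and tested with limma's fry where at least 3 members were present. Mean raw Ct over the 66 target rows below 35 in every sample was compared by exact two-sided permutation tests.

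Other settings fixed before the data were examined were delta Ct recomputed from raw Ct against the mean of the 5 rows with housekeeping labels, each of them alone, or the panel mean of the 66 rows. Others were no Ct filter, a limit of 30, values over 35 set to 35, a fit of the compared groups alone, an intensity trend, replicate blocks, and leaving out each sample. A block by number within day joins samples of both arms, which are different rats, so it cannot pair 2 ears of 1 rat. Only the number within day and arm could do so. Chosen after seeing the data were fits of each day separately, on deposited or panel-mean values, with or without replicate blocks, the raw-table labels for the lists, the Ct limit applied to the compared groups alone, and sponge and antioxidant effects pooled over the other factor. The fit was tested on simulated data with 20 of 79 rows changed in 50 simulations. For ototoxic against control ears at day 3 it recovered 34.3% of rows changed by 1 log2 unit and 79.4% of those changed by 2, with 2.6% and 4.5% false calls. For the same groups at day 21 the recovery was 30.0% and 76.4%. The simulated noise was normal and independent between rows, without a ceiling or tied values. Each simulated row had 1 SD and 1 base level on both days, which real rows of differing order need not have. With 20 rows changed at once, these shares are not the recovery of a single changed row. The labels do not say whether samples of a group came from separate rats, so p-values measure the spread between these samples.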

Results

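Cochlear RNA was profiled in 18 samples at day 3 and 12 samples at day 21 after the sponge. At day 3 there were 3 control, 4 ototoxic, 6 antioxidant and 5 antioxidant plus ototoxic samples, and at day 21 each of the 4 groups had 3. Control and ototoxic ears came from the vehicle arm, and the other 2 groups from rats given resveratrol, a plant polyphenol, with N-acetylcysteine, a cysteine donor. Kanamycin is an aminoglycoside antibiotic and furosemide a loop diuretic, and both are known to damage hearing. Between 0 and 6 of the 84 raw rows per sample stood at the ceiling of 40 cycles. Samples of a group were distinct, with root mean square differences of panel-centred Ct between 0.44 and 1.76 cycles.

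Mean raw Ct, a measure of the amount of template, differed past the threshold in no comparison within a day after adjustment. At day 3 the mean raw Ct over 66 rows was 24.51 ± 0.33 (SD, n = 3) in control ears, 24.72 ± 0.59 (SD, n = 4) in ototoxic ears, 24.20 ± 0.32 (SD, n = 6) in antioxidant ears and 23.99 ± 0.23 (SD, n = 5) in antioxidant plus ototoxic ears. The last group minus ototoxic ears was -0.73 cycles (exact permutation test, two-sided p = 0.0476, 0.268 after Benjamini-Hochberg adjustment over 10 comparisons). At day 21 the means ran from 25.29 to 25.94 cycles, and the smallest p that 3 against 3 samples allow in the exact test is 0.1.

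Gene labels did not follow the values from the raw to the processed table, as the plot of rank correlations per sample shows. The rows labelled as housekeeping genes in the raw table did not behave as 1 set on both days. The row labelled Ldha had a mean Ct of 26.92 ± 0.47 (SD, n = 18) at day 3 and 39.82 ± 0.63 (SD, n = 12) at day 21, and the row labelled Rplp1 had 33.04 ± 2.29 and 36.14 ± 3.42. Assay rows are named below by their raw plate well.

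**Figure D1:**
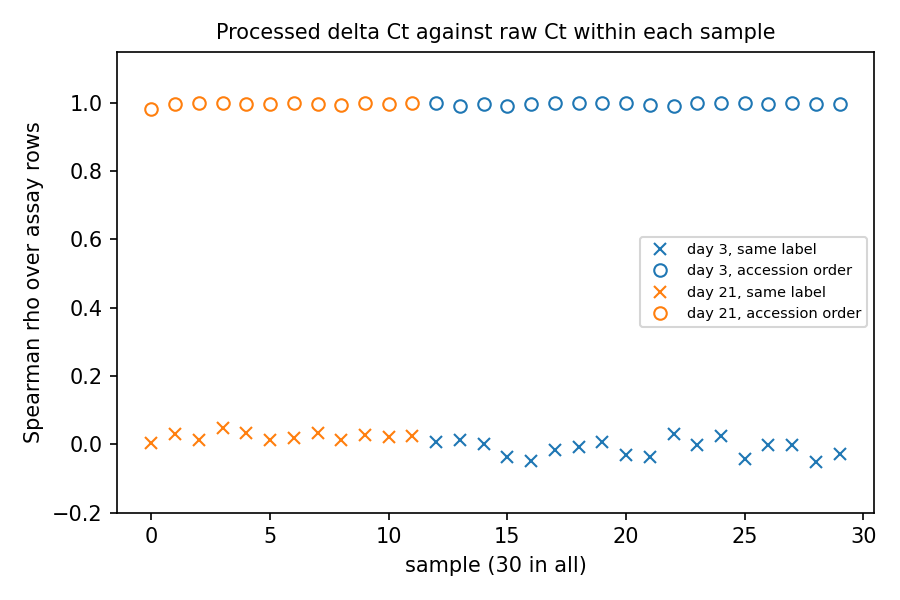
Spearman correlation over assay rows between delta Ct and raw Ct (vertical axis, no unit) for each of the 30 samples (horizontal axis), with rows matched by label (crosses) or by accession order (circles), day 3 in blue and day 21 in orange. Label matching gives values from -0.05 to 0.05 and accession order gives 0.98 to 1.

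The first question was what the ototoxic sponge did in vehicle ears at day 3. limma called 0 of 79 rows at a Benjamini-Hochberg adjusted p of 0.05, and 8 had an unadjusted p under 0.05, where 4 are expected by chance. Among the smallest p-values were those of B01 (raw label Dnm2, processed label Mpp4), E01 (Nxn and Gpx3), C08 (Hbz and Gpx6) and E07 (Prdx4 and Gpx8). Their log2 differences were 1.10, -0.54, 1.30 and 2.87, each with a limma adjusted p of 0.347. B01 was at or over 35 cycles in 2 of the 7 samples, and on panel-mean values of day 3 alone it was 2.97 (SE 1.91). The value of E07 rested on control replicate 1, at the ceiling of 40 cycles, without which it was -0.13. The median half-width of the 95% intervals was 0.89 log2 units. With the panel mean and day 3 fitted alone, chosen after seeing the data, 1 row was called, B12 (Gpx3 and Ppp1r15b), at 1.20 (SE 0.27, limma adjusted p = 0.0362); on deposited values it was 0.29 (limma adjusted p = 0.956), and with either replicate block of the numbers B12 was not called.

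In antioxidant-treated rats, ototoxic ears were set against the ears without ototoxic drugs. No row passed at day 3 in the shared fit of both days, and 8 had an unadjusted p under 0.05 in limma. The rows with the smallest p were C08 at 1.45, G09 (Ucp3 and Mpo) at 1.86, D09 (Noxo1 and Fmo2) at -0.91, D08 (Noxa1 and Ccs) at 1.01 and E11 (Psmb5 and Cygb) at -0.73. The limma adjusted p was 0.0984 for the first 3 and 0.263 for the others. Minus delta Ct of G09 was 1.85 ± 0.58 (SD, n = 5) with the sponge and -0.02 ± 0.63 (SD, n = 6) without it. Without antioxidant plus ototoxic replicate 6, E11 was -0.43. Fitting day 3 alone, chosen after seeing the data, called G09 at 1.86 on deposited values (limma adjusted p = 0.0219) and at 1.91 on panel-mean values (SE 0.37, limma adjusted p = 0.00675). A block by replicate number within day joins different rats across arms. With it the limma adjusted p was 0.0193 on deposited and 0.0504 on panel-mean values. With the number within day and arm, the only reading that could pair ears, the limma adjusted p was 0.0043 and 0.0102.

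Against vehicle control ears, antioxidant plus ototoxic ears at day 3 again had 0 called rows in limma and 9 with an unadjusted p under 0.05. G09 had the smallest p, at 2.43 (SE 0.70, limma adjusted p = 0.157). It was followed by D09 at -0.98, C08 at 1.42, B05 (Ercc2 and Gpx5) at 0.98 and D11 (Nudt1 and Sod1) at 2.13, with limma adjusted p from 0.219 to 0.279. On panel-mean values of day 3 alone B05 was 0.60. Without control replicate 1, D09 was -0.65. Day 3 alone called G09 at 2.43 on deposited values (limma adjusted p = 0.0101) and at 2.28 (SE 0.44) on panel-mean values (limma adjusted p = 0.00778). With the replicate number within day as a block these were 2.62 (limma adjusted p = 0.0208) and 2.51 (limma adjusted p = 0.0586).

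Antioxidant against control ears at day 3 addressed the antioxidants in ears without a sponge. By the protocols, these rats carried the drug-soaked sponge in the other ear. limma called 0 rows, and 3 had an unadjusted p under 0.05. Values of the 5 with the smallest p were 2.74 for E07, 3.59 for C01 (Gpx4 and Noxo1), 1.25 for B02 (Duox1 and Xpa), 0.71 for A03 (Apc and Gpx7) and 1.31 for B04 (Epx and Gpx1), with limma adjusted p from 0.816 to 0.977. Without control replicate 1, E07 was -0.26 and C01 was 1.62. On panel-mean values of day 3 alone A03 was 0.40 and E07 was 5.30. Day 3 fitted alone on deposited values, chosen after seeing the data, called 1 row.

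The antioxidants' effect in sponge-treated ears was the comparison with 1 called row at day 3. Row E01 was higher in antioxidant plus ototoxic ears, 1.04 ± 0.27 (SD, n = 5), than in ototoxic ears, 0.20 ± 0.12 (SD, n = 4). The log2 difference was 0.83 (SE 0.18, 95% interval 0.46 to 1.21, limma adjusted p = 0.00939), or 1.78-fold if deposited values are log2 units. The call was lost with the panel mean (0.32 with day 3 fitted alone, limma adjusted p = 0.489) and under the other raw-Ct references. With the replicate number as a block 0 rows were called. Without ototoxic replicate 5 the difference was 0.79 (limma adjusted p = 0.0535).

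The interaction at day 3, whether the sponge's effect differed with the antioxidants, had 0 called rows in limma and 3 with an unadjusted p under 0.05. They were C04 (Gpx7 and Fancc) at -1.09, B01 at -1.09 and E07 at -3.26, and E01 was at 0.55 with an unadjusted p of 0.0504, each with a limma adjusted p of 0.796. B01 was at or over 35 cycles in 5 of 18 samples, and on panel-mean values of day 3 alone B01 was -4.22, E07 -5.94 and E01 0.22. Without control replicate 1, E07 was -0.26 here too. The median interval half-width was 1.14 log2 units.

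At day 21, row G01 (Sod2 and Noxa1) was lower in ototoxic ears, -2.53 ± 0.19 (SD, n = 3), than in control ears, 0.45 ± 0.54 (SD, n = 3). Its log2 difference was -2.98 (SE 0.73, 95% interval -4.49 to -1.47, limma adjusted p = 0.0334), and it was the 1 called row. Day 21 alone on panel-mean values gave -2.95 (SE 0.43, limma adjusted p = 0.00465). The call was lost with the panel mean in the shared fit, with the replicate number as a block there, and when any of 5 of the 6 samples was left out, at log2 differences from -3.28 to -2.75. The shared fit takes the spread of G01 from both days, where this row need not be 1 assay. Its mean raw Ct was 32.54 at day 3 and 27.36 at day 21.

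**Figure D2:**
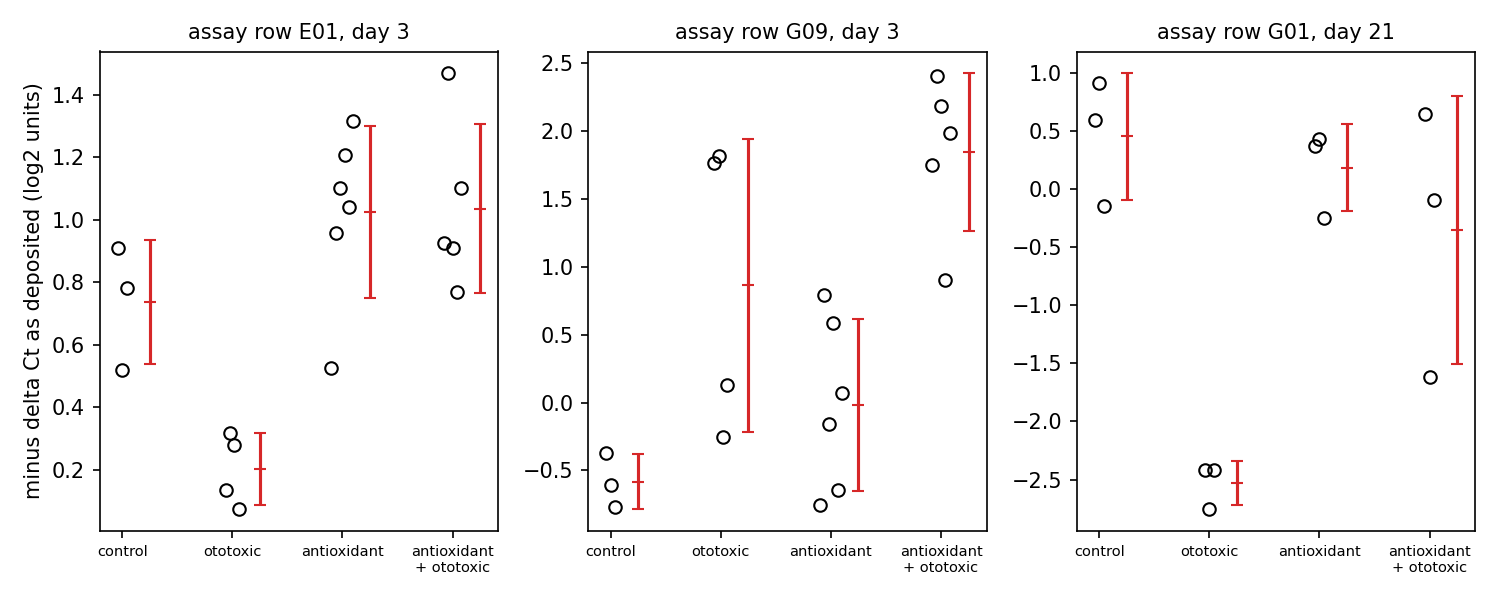
Minus delta Ct as deposited (vertical axis, log2 units, own scale per panel) for assay rows E01 and G09 at day 3 and G01 at day 21 in the 4 groups, with a circle per sample and red bars for the mean ± SD. G01 averages -2.53 in ototoxic ears and 0.45 in control ears at day 21.

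The other comparisons at day 21 had 0 called rows in limma. Up to 25 of 79 deposited values of a sample, in control replicate 1, shared its lowest delta Ct, so panel-mean values of day 21 alone are given where they differ by over 1.5 times. Antioxidant against control ears had 4 rows with an unadjusted p under 0.05. D02 (Mpp4 and Nxn) was at 2.30 (limma adjusted p = 0.122), F12 (Sod1 and Nox4) at 2.96, D10 (Nqo1 and Ncf1) at -0.64 and, with an unadjusted p of 0.0652, D01 (Mpo and Gab1) at -0.97. On panel-mean values D02 was 0.94 (SE 0.56) and F12 was 4.59 (SE 2.33). Leaving out antioxidant replicate 1 or 2 put F12 at 1.48 or 4.55 (limma adjusted p = 0.0298 for the second), and leaving out control replicate 2 put D01 at -0.46. Antioxidant plus ototoxic against control ears had 1 row with an unadjusted p under 0.05, D08 at 1.49. Next were -0.58 for C05 (Gsr and Slc38a5), 1.05 for G08 (Txnrd2 and Prdx2), 0.87 for B09 (Gab1 and Gpx4) and 0.88 for F08 (Slc38a1 and Txnip). On panel-mean values G08 was 0.54, B09 was 0.31 and F08 was 0.25. Without control replicate 1 they were 0.20, 0.09 and 0.20 on deposited values.

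Between antioxidant plus ototoxic and ototoxic ears at day 21, 3 rows had an unadjusted p under 0.05 in limma. G01 was at 2.18 (limma adjusted p = 0.404), D08 at 1.36 and, with an unadjusted p of 0.108, E01 at 0.37, or 0.07 on panel-mean values. Against antioxidant ears, 4 rows had an unadjusted p under 0.05. D02 was at -1.98 (limma adjusted p = 0.371) and D08 at 1.21. In the interaction 5 rows did, with D02 at -2.74 and G01 at 2.44, each at a limma adjusted p of 0.524. Without antioxidant plus ototoxic replicate 3, D08 was 0.92 against control, 0.79 against ototoxic and 0.63 against antioxidant ears, and without ototoxic replicate 3 D02 was -1.78 in the interaction. On panel-mean values D02 was -0.91 against antioxidant ears and -0.96 in the interaction. No differences within day 21 are reported as results for G09 and H04 (Ldha and Ngb), where raw Ct was at the ceiling of 40 cycles in 7 of 12 samples for G09 and, against antioxidant ears, in 6 of 6 for H04.

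Change of the sponge's effect between days was tested last, although a row need not be the same assay on both days. In vehicle ears limma called 0 rows, with 5 at an unadjusted p under 0.05. In antioxidant ears 1 was called, G09 at -3.90 (SE 0.98, limma adjusted p = 0.0405), and it was not called with the panel mean or with the replicate number as a block. G09 had a mean raw Ct of 24.83 at day 3 and 37.52 at day 21, and 5 of the 17 samples were at the ceiling, so the size of this difference is not a measured level. In the authors' deposited table of day differences, between 23 and 25 of 79 rows per group were beyond 4 log2 units, and the antioxidant plus ototoxic column has the opposite sign of the other 3.

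Of the 15 gene lists, 14 had enough members under the labels of the processed table. limma's fry, which tests whether a list's rows move one way on balance, called 0 of 168 list tests over 12 comparisons after Benjamini-Hochberg adjustment, and 1 had an unadjusted p under 0.05. Over all rows, list members were called 2 times, and 8 times adjusted over the list alone. Under the raw-table labels, chosen after seeing the data, 8 of 168 tests had an unadjusted p under 0.05 and 2 tests passed after adjustment. Both were the list of blood, muscle and liver markers at day 3, with antioxidant plus ototoxic ears higher than control ears (median log2 difference 1.29, fry adjusted p = 0.0322) and than antioxidant ears (1.04, fry adjusted p = 0.0395). For ototoxic against control ears at day 3 the median of the same list was 1.37 (fry adjusted p = 0.0962). Its 4 members were C08, G09, C12 (Mb and Park7) and G04 (Tmod1 and Mb), at 1.45, 1.86, 0.64 and 0.24 against antioxidant ears. The 2 passing tests use the same 4 rows and the same antioxidant plus ototoxic samples, so they are not separate results. Since neither label set is settled, these list tests hold for the rows and not for named genes.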

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

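All tests of explanations in this part were chosen and their predictions written only after the results were seen. 45 groups of named rows at day 3 were searched for a sample apart from the others, and 4 stood apart, where chance alone gives about 1 in 20. The gap to the nearest sample over the range was 0.688 for B02 in antioxidant ears (replicate 6, at 4.20 against 3.39), 0.840 for C04 in ototoxic ears (replicate 3), 0.666 for D08 in antioxidant ears (replicate 6) and 0.947 for E07 in ototoxic ears (replicate 5, at 4.32 against 2.76). A difference between days was called for G09 in antioxidant ears, at -3.90, and it sets rows against each other that need not be 1 assay. G09 was at the ceiling of 40 cycles in 5 of the 17 samples, so its size is not a measured level.

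In some fits chosen after seeing the data, row G09 was called higher in sponge ears of the antioxidant arm at day 3. The shared fit did not call it (1.86, limma adjusted p = 0.0984). In vehicle ears the difference was 1.45 (SE 0.73, limma adjusted p = 0.529), and on panel-mean values of day 3 alone 1.49 (limma adjusted p = 0.138). With the number within day and arm as a block these became 2.48 (limma adjusted p = 0.00425) and 2.47 (limma adjusted p = 0.029), on only 2 shared numbers, and with the number within day 1.67 (limma adjusted p = 0.189) and 1.69 (limma adjusted p = 0.434). The covariate test for a difference in the amount of template could not decide, since it used panel-mean values. These already have the mean raw Ct of the same rows subtracted. On them the log2 difference between antioxidant plus ototoxic and antioxidant ears was 1.67 (SE 0.28) with mean raw Ct as a covariate and 1.91 without it. Mean raw Ct of the first group minus the second was -0.21 cycles (exact permutation test, two-sided p = 0.245). A single aberrant sample is argued against, since 5 of 5 antioxidant plus ototoxic samples lay above each antioxidant sample. Blood or muscle tissue in the samples remains a possible explanation: under the raw labels the list holding G09 gave a fry adjusted p of 0.0395, but G09 is itself a member and the labels are unsettled. An effect of the sponge on cochlear cells stays open and cannot be told apart from that.

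Labels of the raw and processed tables disagree. A candidate explanation is that the processed rows were sorted by accession without their labels, and the median rank correlation in that order was 1. Sorting of 1 day by accession, symbol or plate column as the source of the difference between days is argued against, since the highest correlation was 0.29. No biological explanation was tested.

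Delta Ct values piled up at the lowest value of a sample, with up to 25 of 79 rows in control replicate 1 at day 21 and 1 in each day 3 sample. In 12 of the 12 samples of day 21, where at least 2 rows were tied, these were the rows of lowest raw Ct. As delta Ct and raw Ct rank nearly alike in each sample, this had to come out so, and the authors' normalization as a source was left open. No biological explanation was tested.

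Other splits of the same samples were fitted for each count of called rows. Where the real count is 0, each split reaches it by construction, so the test is void and says nothing about chance. This covers ototoxic against control ears at day 3 (35 of 35 splits, highest other 1), antioxidant against control (84 of 84, highest other 3), both against control (56 of 56, highest other 2), both against antioxidant (100 of 100, highest other 9) and the interaction (100 of 100, highest other 6). It also covers the interaction at day 21 (100 of 100, highest other 12), the change between days in vehicle ears (100 of 100, highest other 1) and 4 comparisons at day 21 with 10 of 10 splits. The highest others of those 4 were 10, 0, 1 and 2, in the order antioxidant against control, then both against control, ototoxic and antioxidant ears. The 1 row between antioxidant plus ototoxic and ototoxic ears at day 3 was met in 9 of 100 splits (highest other 3), and the 1 row of the change between days in antioxidant ears in 6 of 100 (highest other 2), so chance could not be excluded for these 2. For ototoxic against control ears at day 21, 10 splits are too few for a share under 0.05. The real count there was 1, met in 3 splits, and the highest other was 5. Some splits called 9 to 12 rows where the real count was 0, and the source of these calls was not tested.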

How the results depend on the processing

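Fits of each day alone with or without a replicate block, the raw labels for lists, the pooled effects and a filter over the compared groups were chosen after seeing the data; the other settings were fixed before the data were examined. The cause was not tested for any change given here. Most comparisons have 0 or 1 called rows, so counts change by single rows. The filter at 35 removed no row and its alternative is void. With rows tested only where at least 1 compared group was below 35 throughout, also chosen after seeing the data, 72 to 79 rows entered and no count of calls moved. H04 and G09 at day 21 are given here though many of their values are at the ceiling, 6 of 6 for H04 and 5 of 6 for G09 against antioxidant ears. With deposited values these 2 were -0.996 and -2.038 there. As raw Ct of H04 is the same in all 6 samples, its difference comes from the normalization alone. The single housekeeping rows are poor references, since their labels are unsettled.

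With the mean of the 5 housekeeping labels the single calls of antioxidant plus ototoxic against ototoxic ears at day 3, ototoxic against control ears at day 21 and the change between days in antioxidant ears went from 1 to 0. Antioxidant plus ototoxic against antioxidant ears at day 21 went from 0 to 1. Signs turned at day 21 for D10 (0.46, antioxidant against control), C05 (0.27, both against control) and H04 (0.28, both against antioxidant). The panel mean in the shared fit also took those 3 calls to 0, and turned H04 (0.65). Capping Ct at 35 with the housekeeping mean gave 1 row for antioxidant against control at day 3, 5 for both against control, 2 for both against antioxidant, and 0 for both against ototoxic and for ototoxic against control at day 21. There G09 turned to 0.12 and H04 to 0.28 against antioxidant ears at day 21.

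Single housekeeping labels gave at most 1 row for ototoxic against control at day 3, 2 for both against control, 5 for both against antioxidant and 1 for antioxidant against control at day 21. They gave 0 at most and at least for both against ototoxic at day 3 and for ototoxic against control at day 21, and at least 0 for the change between days in antioxidant ears. Their highest values turned E01 (1.54) in ototoxic against control ears, D09 (0.93) and E11 (0.038) at day 3, and D10 (4.11), D01 (3.46), C05 (3.47) and H04 (0.82) at day 21. Their lowest turned E01 (-0.99) in the interaction at day 3. At day 21 they turned B09 (-0.024) and F08 (-0.09) in both against control, E01 (-0.23) in both against ototoxic, and G01 (-0.61) in the interaction.

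In fits of the compared groups alone, 1 row was called for both against control and for both against antioxidant at day 3, for antioxidant against control and both against antioxidant at day 21, and for the change between days in vehicle ears. The call of both against ototoxic ears at day 3 went to 0, where fewer samples were in the fit. Each day fitted alone on deposited values gave 1 for antioxidant against control, both against control and both against antioxidant at day 3. On panel-mean values it gave 1 for ototoxic against control, both against control and both against antioxidant, 0 for both against ototoxic, and turned H04 to 0.65 at day 21. The raw labels gave 1 list in place of 0 for both against control and both against antioxidant at day 3. For the pooled effects, the panel mean gave 7 in place of 2 for the sponge and 0 in place of 2 for the antioxidants at day 3, and 1 in place of 0 for the sponge at day 21.

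The numbers were not taken to pair the samples. Labels name the other ear as the control but do not say that equal numbers mark 1 rat. Same-number correlations of deviations on deposited values ran from 0.08 to 0.66 (Pearson) and from 0.15 to 0.43 (Spearman) over 5 pairs of the antioxidant arm at day 3. The choice of coefficient there decides whether each pair exceeds 0.1, and with the panel mean all 5 did. As a hint from the data, 4 of those 5 sponge samples on deposited values correlated best with their own number, and 0 of 3 did in either arm at day 21. At day 21 they ran from -0.56 to -0.11 (Pearson) over both arms. The arms are different rats, so the number within day also joins samples that cannot be of 1 rat. With the number within day as a replicate block the count went from 1 to 0 for both against ototoxic at day 3, ototoxic against control at day 21 and the change between days in antioxidant ears, and no other count of calls moved. The block in fry and the random block changed no count.

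Replicate blocks in fits of each day alone were added last, after the calls of the other fits were known, and use both blocks. Of these, only the number within day and arm could mark 1 rat. With the number within day, deposited values gave 1 row for antioxidant against control, 1 for both against control, 0 for both against ototoxic and 2 for both against antioxidant at day 3, and panel-mean values gave 0 in each of them and for ototoxic against control. G09 then had a limma adjusted p of 0.0193 on deposited and 0.0504 on panel-mean values against antioxidant ears, and 0.0208 and 0.0586 against control ears. With the number within day and arm, where only contrasts inside an arm can be fitted, ototoxic against control ears at day 3 had 2 rows on deposited and 3 on panel-mean values, but only replicates 2 and 3 are shared there. There E07 turned to -0.541 and -0.946, and in the interaction, with 1 and 0 rows, to 0.253 and 0.64. Both against antioxidant had 2 and 2, with G09 at 1.715 (limma adjusted p = 0.0043) and 1.858 (limma adjusted p = 0.0102). Ototoxic against control at day 21 had 0 and 1 rows with the number within day and arm, and 1 and 1 with the number within day. H04 was 0.647 on panel-mean values under both. The pooled sponge effect of day 3 had 3 and 3 rows with the number within day, and 4 and 9 within day and arm, and the pooled antioxidant effect had 0 and 0.

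Leaving out 1 sample moved counts between 0 and 1. Ototoxic against control at day 3 and the change between days in vehicle ears reached 1 without ototoxic replicate 4 of day 3. Both against ototoxic at day 3 fell to 0 without ototoxic replicate 5. Ototoxic against control at day 21 fell to 0 without any sample but control replicate 3. Antioxidant against control at day 21 reached 1 without antioxidant replicate 2 or 3, both against antioxidant without replicate 1 or 3, both against control without antioxidant plus ototoxic replicate 2, and the interaction without antioxidant replicate 3. The change between days in antioxidant ears was lost in 12 of 17 cases. E07 ranged from -0.13 to 4.44 in ototoxic and from -0.26 to 4.31 in antioxidant against control ears at day 3, and H04 from -1.58 to 0.16 at day 21.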

Other observations

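Effects pooled over the other factor were computed after the data were seen, as were their tests, with each day fitted alone. At day 3 the sponge effect on deposited values had 2 called rows in limma, G09 at 1.65 (SE 0.33, limma adjusted p = 0.00815) and C08 at 1.37 (SE 0.31, limma adjusted p = 0.0155). With the panel mean it had 7, of which 4 were higher and 3 lower. Among these were G09 at 1.70, B12 at 0.92, C08 at 1.33, C12 at 1.94, D09 at -0.68 and A03 at -0.39, at limma adjusted p from 0.00232 to 0.0463. On deposited values B12 was 0.30 (limma adjusted p = 0.458), C12 was 1.38 (limma adjusted p = 0.424), D09 was -0.76 (limma adjusted p = 0.163) and A03 was -0.11 (limma adjusted p = 0.835). Of 100 splits within arms, only the real one gave as many rows in each case, 1 of 100 against a highest other of 1 on deposited values and of 2 with the panel mean. With the replicate number within day as a block the count was 3 on deposited and 3 on panel-mean values, and with the number within day and arm it was 4 and 9. G09 was called in all 4 of these fits, from 1.75 to 2.17. The pooled comparison was picked after several others had called nothing, and the splits ignore replicate numbers, so that share does not exclude chance.

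The pooled antioxidant effect at day 3 had 2 called rows on deposited values, B02 at 0.77 and E01 at 0.56 (limma adjusted p = 0.0408 for both), met by 1 of 100 splits (highest other 1), with the same limit. With the panel mean B02 was 0.70 (limma adjusted p = 0.0808) and E01 was 0.21 (limma adjusted p = 0.470), and with the replicate number within day as a block 0 rows were called on either set of values. With the panel mean it had 0, with 6 at an unadjusted p under 0.05, and 100 of 100 splits gave as many (highest other 1). At day 21 the sponge effect had 0 on deposited values (2 at an unadjusted p under 0.05; 100 of 100 splits, highest other 11) and 1 with the panel mean, G01 at -1.77 (limma adjusted p = 0.0166; 6 of 100 splits, highest other 2), or 1 and 0 with the replicate number within day, or within day and arm, as a block. Behind the pooled -1.77, G01 was -2.95 in vehicle ears and -0.595 (limma adjusted p = 0.852) in antioxidant ears on panel-mean values of day 21 alone. The antioxidant effect at day 21 had 0 on both sets of values, with 3 and 10 rows at an unadjusted p under 0.05 in limma (100 of 100 splits each, highest others 8 and 2). Each split reaches a count of 0 by construction, so those shares say nothing about chance.

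Some rows varied widely within groups at day 3. With the panel mean, the SD within groups was 2.32 for E05 (Prdx2 and Nqo1) and 2.18 for G11 (Xpa and Ercc2), at mean Ct of 23.45 and 24.57. E05 ran from -4.19 to 3.91 among antioxidant plus ototoxic samples and G11 from -4.16 to 2.65. Of the rows named earlier, E07 and C01 had larger SDs of 3.92 and 3.5, at mean Ct of 23.3 and 24.41. E07 had 1 sample at the ceiling, and C01 ran from -10.19 to 4 among ototoxic samples. These rows were chosen after their values were seen, and no explanation was tested.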
